A study of Schistosoma mansoni with 12 samples.

How the data were processed

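Total RNA of adult worms treated with TGF-beta and of a pool of untreated worms was amplified, labelled and hybridised to two-colour Agilent arrays, per the labels' protocols. The deposited scanner files hold, per the file headers, spot intensity in both channels from Agilent Feature Extraction 9.5.1.1. They also hold Agilent's processed intensity, from which a spatial background surface was subtracted and which was dye-normalized by lowess, per the file headers. A log10 ratio of red over green per spot, also deposited by the authors per the file headers, was not used here. A deposited value table gives log2 values without any statement of scale, centring or direction. Set against the scanner files, its columns correlated with the log2 treated/control ratio of the processed signals at 0.998961 to 0.999836 over the 12 arrays, so the direction follows from the values. A correlation leaves the scale open. The 4 probes named below had equal mean log2 ratios from both sources, such as -2.602 for Q2_P12040, so the scale is log2 as well. The medians of its 12 columns ran from -0.14 to 0.23, so the columns are not centred on 0.

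Mean signal and median local background were corrected with normexp (offset 50) and normalised by loess within each array in limma 3.58.1 under R 4.3.3. The 1417 control spots had weight 0 in loess. Spots flagged as outliers, 1181 over the 12 arrays, were left out. Ratios were turned to treated over control on every array and spots of 1 probe were averaged. Probes were kept where the treated or the control channel was well above background on at least 6 arrays (14066 probes), and 22 of these without an unflagged spot in some sample were left out. The 4 arrays of each treated RNA were averaged, so n = 3. The mean ratio was tested against 0 with limma's moderated test with an intensity trend and Benjamini-Hochberg adjustment at 0.05. Each SE given is limma's moderated one, which borrows spread from other probes. It can lie under or over the SE of the 3 samples alone. The pool is 1 control sample, so this test leaves out the control's own spread. The labels call the treated samples biological replicates but name no animals or cultures. The titles of 3 of the 4 arrays of sample 5 carry the biological replicate number of sample 4, while the source names and the rest of the titles give sample 5; samples 4 and 5 were kept apart here, and n = 3 rests on that. In any case p-values measure the spread between these samples, which could be technical in part. Differences among treated samples were tested by a moderated F test on 12 arrays with a dye term, and dye effects by that term. Slide and treated sample coincide. The 3 treated RNA samples and the 1 pool limit the precision of the main test, and the number of arrays limits that of the F test.

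Named probes followed a rule set before the data were examined. Without gene names it takes the 2 probes with the largest rise and the 2 with the largest fall among those called, with 1 sign in all 3 samples and both dye orientations. The limit of 1 per sequence family was added after the data were examined. The files pair no probe with a gene name, and 0 of the 41739 probe names occur in the RefSeq gene table with 13257 genes. The 22 gene lists fixed beforehand could therefore not be applied. Sequence families, made after the data were examined, join probes that share at least 20 bases on 1 strand and are tested as the mean of their tested probes. Probes were joined in chains, so members need not all hold the same stretch, and a family is named by its most frequent 20 bases. A bound for a dim probe is the control's mean over the higher of the probe's own treated signal and the lowest treated signal well above background, per channel after loess and Aquantile.

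The main test was tested on simulated data for 14044 probes with 200 changed. It recovered 57% of 100 probes changed by 1 log2 unit and 98% of 100 changed by 2, with 13 wrong calls among 168, and made 0 calls when nothing changed. These simulated samples varied independently and leave out the pool they share. Alternatives covered the filter, background, normalization, value table, each sample and array left out, dye orientation, a random block for the RNA sample, the control's spread, the trend, saturated spots and the threshold. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.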

Results

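Adult worms of the blood fluke Schistosoma mansoni, perfused from hamsters 45 days after infection, were cultured overnight with 1 nM TGF-beta, a secreted growth factor that signals through receptor kinases and Smad proteins, or with vehicle. RNA of 3 treated samples, numbered 1, 4 and 5 in the labels (some titles of sample 5 repeat the biological replicate number of sample 4), was compared with 1 pool made from 2 untreated samples. Each treated RNA was hybridised with the pool on 4 two-colour Agilent arrays, 2 with the treated RNA in Cy5 and 2 with it in Cy3, giving 12 arrays. The arrays carried 41739 probes of 60 bases with 40965 distinct sequences. Between 8556 and 14530 spots per array were well above background in the treated channel, and between 12671 and 15388 in the control channel. Treated sample 4 had 9741 ± 1373 such spots (SD, n = 4 arrays), against 13785 ± 660 in sample 1 and 12659 ± 574 in sample 5. The control pool gave 14386 ± 1087, 14410 ± 1008 and 13839 ± 1121 on the arrays of samples 1, 4 and 5. The scanner files name no gene for any probe, so probes are given by identifier and sequence, and values are log2 ratios of treated over control.

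**Figure D1:**
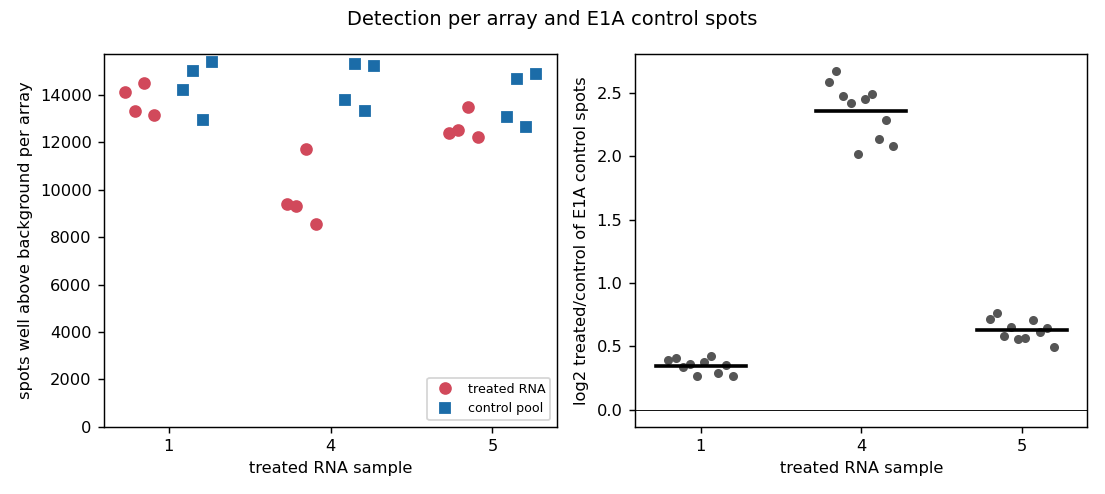
Left, the number of spots well above background per array (vertical axis, starting at 0) for treated RNA (circles) and the control pool (squares), by treated sample. Right, the log2 treated/control ratio of the 10 E1A control probes, each averaged over 32 spots and over the arrays of a sample (points, mean as a bar). Sample 4 has 9741 treated spots above background on average and a mean E1A ratio of 2.36. In samples 1 and 5 the E1A ratio was below 0 on arrays with treated RNA in Cy5.

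The first comparison asked which transcripts differed between treated worms and the control pool. Of 14044 probes tested, 570 were lower and 56 were higher in treated worms, so 91.1% of the 626 calls were falls (limma, Benjamini-Hochberg 0.05). The median change was -0.78 among the falls, which ranged from -2.51 to -0.40, and 0.72 among the rises, which ranged from 0.49 to 1.08. A change of at least 2-fold was seen for 121 of the falls and 1 of the rises. Each of the 626 probes had the same sign in 3 of 3 treated samples and in both dye orientations. Among all probes tested, 52.5% had 1 sign in the 3 samples. A probe whose signs differ among 3 samples spreads too widely to be called here. The call itself therefore fixes the shared sign, which is no separate support. The treated signal was well above background on all arrays for 353 of the 570 falls, and on only some or none for the rest. For 14 of the falls it was not well above background on any array. For these 14 only a bound holds, at least 1.18-fold to at least 1.62-fold lower.

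With the standard error widened for the pool's own spread, limma called 0 probes, the lowest adjusted p was 0.227 and 1611 probes had an unadjusted p under 0.05. Calls numbered 17 without sample 5, 81 with Agilent's processed signals, 1158 with median centring, 1755 without sample 1, 3806 with the RNA sample as a random block and 4144 without sample 4. Of these, 38.8% were rises without sample 4, 32% with the random block and 27.4% without sample 1, and at an unadjusted p under 0.05 there were 2980 falls and 1276 rises.

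The largest measured fall among the calls was that of probe Q2_P12040, with the sequence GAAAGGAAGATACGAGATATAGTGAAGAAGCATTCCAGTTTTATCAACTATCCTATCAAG. Its mean log2 ratio was -2.51 (moderated SE 0.408, n = 3, limma adjusted p = 0.0414), with -1.20 in sample 1, -3.27 in sample 4 and -3.08 in sample 5. The SD between these samples was 1.14. Probe Q2_P02361, with the sequence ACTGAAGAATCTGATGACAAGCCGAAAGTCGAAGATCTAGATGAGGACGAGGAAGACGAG, was also lower. Its measured log2 ratio was -2.30 (moderated SE 0.400, n = 3, limma adjusted p = 0.0430), with -1.09 in sample 1, -2.96 in sample 4 and -2.86 in sample 5 (SD 1.05). However, its control signal was saturated on 10 of 12 arrays, so its rank against Q2_P12040 is not settled. Over all alternatives the adjusted p ran from 1.43e-13 to 0.394 for Q2_P12040, with 5 of 29 past no threshold, and from 1.5e-09 to 0.394 for Q2_P02361, with 6 of 28. Both low ends came from limma without sample 1, which rests on 2 samples. Both probes also differed among the 3 treated samples, with adjusted p of 9.28e-11 and 5.43e-08 in limma's F test. The largest called rise was that of probe Q2_P19267, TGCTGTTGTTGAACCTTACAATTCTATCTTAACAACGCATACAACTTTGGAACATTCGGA, at 1.08 (SE 0.189, n = 3, limma adjusted p = 0.0430). It was 1.08 in sample 1, 0.62 in sample 4 and 1.55 in sample 5 (SD 0.46). Probe Q2_P22836, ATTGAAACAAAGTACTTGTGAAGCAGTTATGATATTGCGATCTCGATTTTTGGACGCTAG, rose by 0.99 (SE 0.131, n = 3, limma adjusted p = 0.0360). With median centring, where the median of all probes was -0.56, these rises were 0.34 and 0.30 and passed no threshold (limma adjusted p = 0.698 and 0.718). Over all alternatives the adjusted p ran from 8.86e-06 to 0.937 for the first and from 0.000288 to 0.852 for the second. Both low ends came from limma on 12 arrays with the RNA sample as a random block, though there were only 3 treated RNA samples. Scaling to the E1A control spots moves the median of all probes to -1.20 and, by that shift, these 2 ratios to -0.072 and -0.17.

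Some probes share a stretch of 20 bases with another probe and were chained into sequence families. This grouping was made from the probe sequences after the data had been examined. Members need not all hold the same stretch, so a family is named by its most frequent 20 bases. Whether a family covers 1 transcript is not known, since no probe has a gene name. There were 27 such sequence families with at least 5 tested probes, and 7 of them were lower in treated worms, with none higher. Falls were more frequent among these families (25.9%) than among the other 13135 units (3.73%; Fisher's exact test, two-sided, p = 4.82e-05), though means of several probes were set against mostly single probes. The excess was absent with median centring (11.1% against 7.47%, exact p = 0.451). With Agilent's processed signals 0 families passed, but only 4 of the other 13135 units were called lower, too few to assess an excess. The family named GTGGTAGAACAGGTTGAATC was at -1.54 (SE 0.144, n = 3, limma adjusted p = 0.0375), where 8 of 9 probes were called. That stretch is in 7 of its 9 probes, and 1 of its probes was not well above background in any treated array. The family named ACATATGATGTGGTCTAGTG was at -1.13 (SE 0.116, n = 3, limma adjusted p = 0.0375), with 12 of 12 probes called and values from -1.19 to -1.05 in the 3 samples. Of these 12 probes, 7 hold that stretch. All 5 probes of the family sharing AAAACGAACAGTGATATTGG, which hold 2 distinct sequences, were called, with a family mean of -1.07. The families named AACGTGGTGAGATGAGTTTC (in 4 of 6 probes), AAAAACAGTGTGAATACGAA (8 of 10) and ATTTCTGATTACGGTGTATC (10 of 16) were at -0.92, -0.91 and -0.90. The family sharing ATCCATCGGTTGTGTAGTCG was at -0.66. The last was at -0.38 on the arrays with treated RNA in Cy5 alone (adjusted p = 0.0947), and its adjusted p ran from 0.0091 to 0.42 over 27 alternatives, with 10 past no threshold. The family named AACGTGGTGAGATGAGTTTC also had 1 probe not well above background in any treated array. Its treated signals, and those of the family named ATTTCTGATTACGGTGTATC, were above background on a median of 4.5 and 5 of 12 arrays. With Agilent's processed signals these 2 families were at -1.95 and -2.05, and the family named GTGGTAGAACAGGTTGAATC was at -2.01, none past the threshold. With the pool's own spread allowed for, 0 families passed, with a lowest adjusted p of 0.265 over all units; without sample 5, and with Agilent's processed signals, 0 passed as well.

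**Figure D2:**
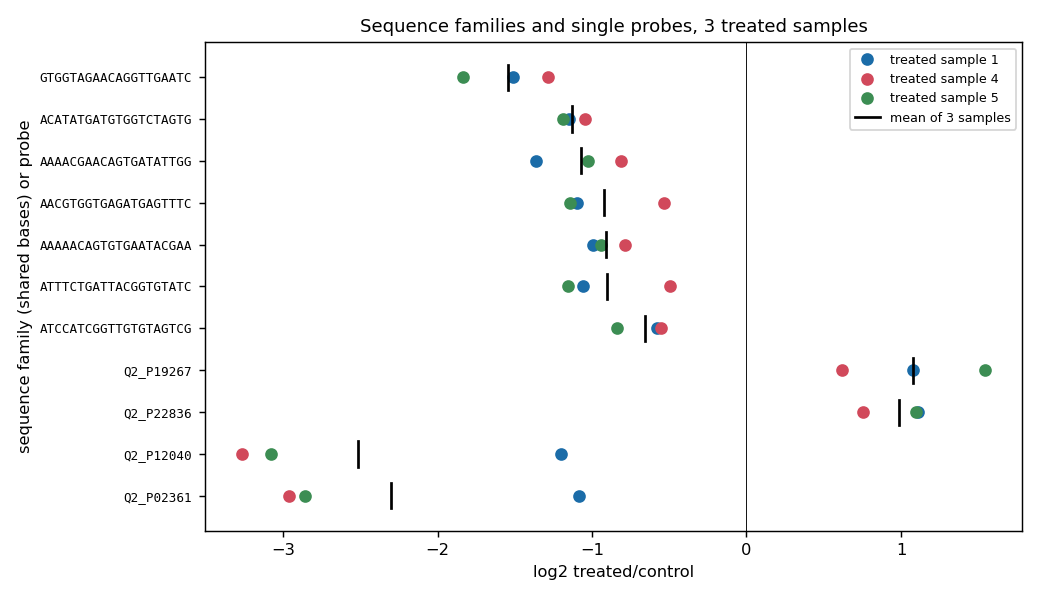
Log2 treated/control ratios (horizontal axis) of the 7 sequence families that fell and of the 4 named probes. Each family is named by its most frequent stretch of bases, which not all of its probes need hold. Points are the 3 treated samples and the bar is their mean. The 7 families lie between -1.83 and -0.49 in every sample.

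The second comparison asked whether the 3 treated RNA samples differed from each other by more than repeat arrays of the same RNA. They differed at 8101 probes, 57.7% of those tested (limma F test with a dye term). Samples 1 and 4 were farthest apart, with 7537 probes differing and 1134 of them by more than 1 on the log2 scale. Samples 4 and 5 differed at 6269 probes and samples 1 and 5 at 2622. Across probes, which are not independent replicates, the ratios of samples 1 and 4 had a Pearson r of 0.163, against 0.723 for samples 1 and 5 and 0.547 for samples 4 and 5. These correlations share the pool: in 100 simulated draws without any effect the mean of the 3 correlations averaged 0.208, with a central 95% from -0.356 to 0.931, and was 0.478 here. The family named ACCAGTTGAGTTGTGGATCA was at -0.66 in sample 1, 1.84 in sample 4 and 0.12 in sample 5. All 16 of its probes differed among the samples, and 9 of them hold that stretch. The family named TGGTGGAGATTGTGGTAATT was at -0.93 in sample 1, 1.79 in sample 4 and -0.55 in sample 5. Here 11 of 11 probes differed, and 10 hold that stretch. Probes of both families were saturated on up to 11 arrays, so these ratios are measured values that saturation limits. The 527 probes of like brightness (mean log2 intensity over 14) had a median of 0.50 in sample 4, against -0.069 in sample 1. Of the 626 probes called against the pool, 299 also differed among the treated samples. Slide and treated sample are the same split of the arrays.

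**Figure D3:**
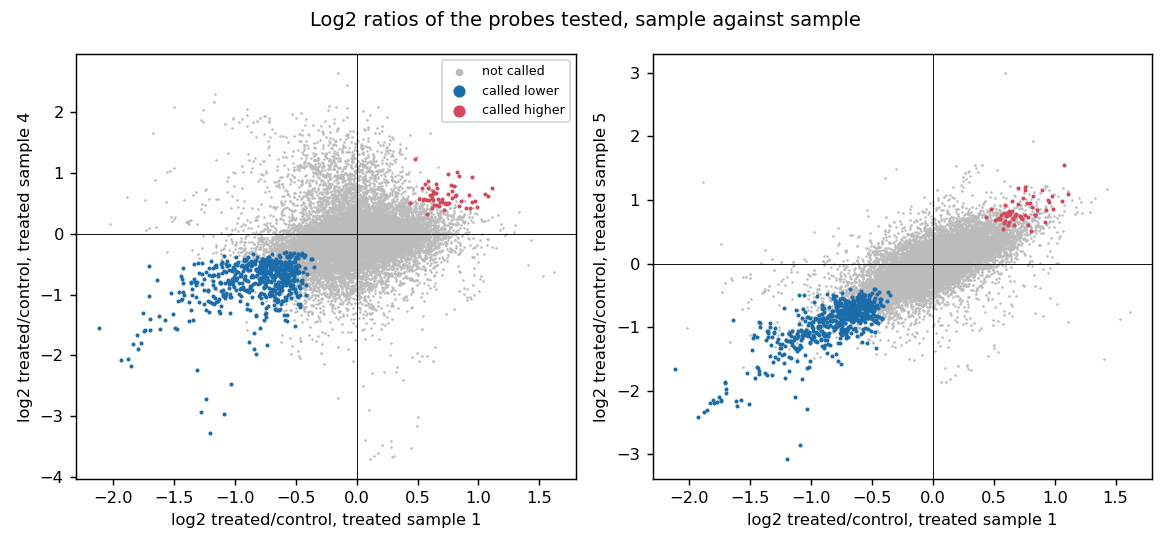
Log2 treated/control ratios of the 14044 probes tested in treated sample 1 (horizontal axes) against sample 4 (left) and sample 5 (right); points are probes, blue for the 570 called lower and red for the 56 called higher. The cloud is narrower for samples 1 and 5 (r = 0.723) than for samples 1 and 4 (r = 0.163).

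The dye swap allowed dye bias to be measured. A dye effect was found at 3063 probes, 21.8% of those tested, with a median size of 0.18 log2 units per orientation among them. It cancels in the mean of 2 arrays of each orientation.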

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

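The tests of the repeated sequences, of the worm RNA amount and of the dye were chosen after the results they bear on had been seen. So was the restriction of the opposite-strand test to the called families, and the forms of the opposite-strand and slide tests were settled after another form of each had been seen.

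A signal lay in control spots that no comparison used. The 10 E1A probes of 32 spots each, Agilent's spike-in controls by their names, averaged a log2 treated/control ratio of 0.35 ± 0.06 (SD over 10 probes) in sample 1, 2.36 ± 0.22 in sample 4 and 0.63 ± 0.08 in sample 5. Each of the 10 was above 0 in all 3 samples, averaged over arrays. On single arrays of samples 1 and 5 the median E1A ratio changed sign with the dye. In sample 1 it was -0.75 and -0.88 with treated RNA in Cy5, and 1.53 and 1.65 with it in Cy3. In sample 5 it was -0.41 and -0.53, and 1.72 and 1.77. Only sample 4 was above 0 in both orientations, at 1.42 and 1.04, and 3.77 and 3.5. Without background correction and with median centring, the means were 0.35, 0.97 and 0.38, so the size in sample 4 depends on the processing. The labels do not say whether the E1A RNA was added in equal amounts to each labelling, so the shift cannot be read as an amount of worm RNA. No explanation was tested for it.

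Most called probes were lower in all 3 treated samples. With each sequence family counted as 1 unit, 497 of 555 calls were lower, which argues against a few sequences counted many times. Of the 4 sign patterns of 3 samples, the real one gave 626 calls and the highest other gave 0; 4 patterns are too few for a share under 0.05. The control pool's own deviation stays open and is a candidate explanation: 22 of 100 draws without any treatment effect called as many probes. The mean covariance of the sample ratios was 0.0879, against 0.0403 in those draws, whose central 95% ran from -0.0935 to 0.296. An effect of TGF-beta stays open too, since 1 pool cannot separate it from the pool's deviation.

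Sequence families with many probes fell in all 3 treated samples. Less worm RNA in the treated samples stays open: of the 7 called families, 0 fell most in sample 4, and loess removes an overall shift. With Agilent's processed signals 2 fell most in sample 4, and with median centring 7 did. Scaling to E1A spots also gave 7, but it subtracts far more from sample 4 than the families differ among samples. That outcome was fixed by the scaling and decides nothing. Only 2 of the 7 had every probe above background on all treated arrays. Genomic DNA in the control pool stays open as well. Over the 49 fallen probes of 6 called families that have an opposite-strand partner, the partner's control signal was a median 0.675 of the missing signal (quartiles 0.249 and 0.953), and 11 reached 1. The bound set before the data were examined covered all 110 fallen probes with a partner, where the median was 0.259 with an upper quartile of 0.69. These values met that bound, by which genomic DNA would have been argued against. It was set aside after the values were seen, since 61 of those probes lie outside the families. Opposite-strand probes also differ in brightness by a median of 3.04 log2 units, so neither median decides the question. A treatment effect stays open too.

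Treated samples 1 and 4 moved apart. The difference of sample 4 minus sample 1 correlated at 0.924 across probes between the dye orientations, which argues against a dye effect. Treated signals differed between these slides 3.8 times as much (SD across probes) as the control pool's, in both dyes (4.03 and 4.31 times with each channel quantile-normalised), which argues against a difference between the slides. Of the probes above background on all arrays, 68.2% differed among the samples, against 43.8% of the rest, so differences were not confined to dim probes. These shares cannot decide on dim signal of treated sample 4. Ratios spread less among the rest (SD of sample 4 minus sample 1 of 0.397, against 0.694), and the F test covers all 3 samples. A difference between the worms, or in the handling of the RNA before hybridisation, stays open and was not tested.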

How the results depend on the processing

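The sequence families, the scaling to E1A spots and the other joining lengths were added after the data had been examined; other alternatives were set beforehand. Causes were not tested unless stated. The 626 calls (570 lower, 56 higher, 7 families) moved as follows. Probes above background in both channels on all 12 arrays gave 350 calls, 308 lower, and 4 families, over fewer probes. Agilent's processed signals gave 81 (74 lower, 7 higher, 0 families) and the deposited values gave 95 calls (87 lower, 8 higher, 0 families). Median centring gave 1158 (1154 lower, 4 higher, 3 families) with a median of -0.56 over all probes, and only 213 of them were among the 626. Scaling to E1A spots gave 5 (5 lower, 0 higher, 0 families), with 2 among the 626. Leaving out a treated sample gave 17 to 4144 calls, 17 to 2536 lower, 0 to 1608 higher and 0 to 15 families; the lowest was without sample 5, the highest without sample 4, and without sample 1 there were 1755. Leaving out 1 array gave 445 to 715 calls, 416 to 649 lower, 29 to 84 higher and 6 or 7 families. Arrays with treated RNA in Cy5 alone gave 959 calls, 184 higher, and in Cy3 alone 1098, 932 lower and 166 higher. The 12 arrays with the RNA sample as a random block gave 3806 (2589 lower, 1217 higher), 619 of them among the 626. Allowing for the control's own spread gave 0 calls, 0 lower, 0 higher and 0 families. A wider error can only lower these counts, but 0 was not fixed beforehand. Without an intensity trend there were 133 (126 lower, 7 higher, 2 families). A threshold of 0.01 gave 0 calls, 0 lower, 0 higher and 0 families, and 0.1 gave 2561 (1945 lower, 616 higher). No background correction, Aquantile, no filter and leaving out saturated spots kept the total within 1.5 times, as did 1 unit per family. In that order, the first 4 of these shared 563, 622, 492 and 625 calls with the 626. Families joined by 18, 25 or 30 bases gave 6, 7 and 6.

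The excess of falls among sequence families was absent with median centring (exact p = 0.451). It was also absent, with 0 families lower, with Agilent's processed signals, the deposited values, scaling to E1A spots and without sample 5. At a threshold of 0.1 it was 29.6% against 14% (exact p = 0.0446). The 8101 probes that differ among samples stayed within 1.5 times under the other filters, backgrounds, normalizations and Agilent's processed signals. Leaving out a sample gave 3095 to 7246, lowest without sample 4. This count was not recomputed under the remaining alternatives. The 3063 dye effects fell to 36 under median centring and ran from 882 to 2528 on leaving out a sample. Of 308 recomputed ratios of named probes and called families, 239 kept their side of the threshold, 67 kept the direction only and 2 turned: Q2_P19267 to -0.072 and Q2_P22836 to -0.17, scaled to E1A spots, which shifts all probes of an array alike and so tests neither probe. No paired analysis was possible because the only control is 1 pool. The gene lists with their alternatives, and 1 probe per gene, were not run because no probe has a gene name. Signal over background limits sample 4 most, with 8556 to 11723 treated spots above background per array.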

Other observations

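All values in this part were computed after the data had been examined. A set of 24 bright probes from 14 sequence families was picked as lying under -2 in sample 4 and above 0 in sample 1. Their median log2 ratio was 0.30 ± 0.17 in sample 1 (SD over probes), -2.95 ± 0.67 in sample 4 and -1.31 ± 0.50 in sample 5, and all 24 were below 0 in sample 5. All 24 were well above background in both channels on all 12 arrays. Differences between samples 1 and 4 follow from how the probes were picked. Low values in sample 5 are not independent of the pick, since samples 4 and 5 share the pool and their ratios correlated at 0.547. Of the 24 probes, 0 were called against the pool. The lowest in sample 4 has the sequence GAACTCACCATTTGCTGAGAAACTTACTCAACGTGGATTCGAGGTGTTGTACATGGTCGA, with 0.11 in sample 1, -3.70 in sample 4 and -1.86 in sample 5.

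Probes that share a stretch of at least 20 bases on opposite strands had correlated ratios. Among 172 such pairs with both probes tested, no family in more than 1 pair and 7 of them exact complements, the log2 ratios correlated across pairs with a Pearson r of 0.662 and a Spearman rho of 0.69 (permutation test, two-sided, p = 1e-05 for each, the smallest that 100000 resamples can give). Without the 2 pairs farthest from the median, r was 0.647. The signs were the same in 124 pairs, 72.1%, against 50.7% for random pairs. The brighter probe of a pair exceeded the dimmer one by a median of 3.04 log2 units of mean intensity. In 20 pairs the brighter probe alone was called, and in 0 pairs both were. No explanation was tested for this.

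With the brightest probe and its own call standing for each family, 491 of 13162 probes were lower, a count that differs from that of tested family means. Of these 14.7% had no open reading frame over the probe on its own strand, against 12.1% of the 12671 others. The difference was not past the threshold (Fisher's exact test, two-sided, p = 0.0912; 95% interval of the odds ratio 0.954 to 1.62).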
